A study of Mus musculus with 16 samples.

How the data were processed

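RNA was sequenced from sorted mouse cells after experimental bacterial pneumonia: macrophages labelled M1 or M2, with or without platelet depletion, blood platelets, single regulatory T cells (Tregs) and Treg-platelet aggregates. Per the labels' protocols, reverse transcription started from the polyA tail and single-end reads of 50 bases were made. The deposited table holds expected counts per gene symbol, per the submitters' processing notes from Salmon 1.0.0 after Trim Galore 0.6.4, with FastQC, MultiQC and DESeq2 listed without a role and mm10 as the genome build. The annotation release, the Salmon settings and the way of summing to genes are not stated there. The values are fractional, start at 0 and have column totals that differ between libraries, so they were treated as unscaled expected counts.

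The table has 50434 genes and 32 columns, with 2 columns for each of the 16 libraries. The median chi-square between the columns of a library was 0.023 to 0.1, where sampling noise alone gives 0.455, and the total of the second column was 0.9937 to 0.9971 of the first. The columns were therefore not treated as separate samples, and the first column of each library was counted once. Of the symbols, 48818 (96.8%) were matched to GENCODE M21, which gave the mm10 positions. No gene of the table lies on chromosome X, Y or M in that annotation, so genes there were not analysed here.

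Groups, comparisons, tests, gene lists and the naming rule were fixed before the data were examined. Macrophage comparisons used 1 fit of 10 libraries in 4 groups, and the Treg and platelet comparisons used 1 fit of 6 libraries in 3 groups. Genes were kept with at least the CPM (counts scaled to library size) of 10 counts in the median library in at least 3 libraries (2 in the Treg and platelet fit) and at least 15 counts in all. Counts were normalised by TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The common dispersion was 1.21 in the macrophage fit, with 6 residual degrees of freedom, and 2.34 in the other fit, with 3. Groups with 1 library have no replicate check and were assumed to vary like the other groups of their fit. Nothing in the labels says that replicates come from separate animals, so p-values measure only the spread between these samples. By chance alone, a share of about 0.05 of the tested genes has an unadjusted p under 0.05. Counts of such genes are to be read against that share.

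The 26 gene lists covered macrophage states, inflammation, lipid mediators, metabolism, antigen presentation, T cell functions and markers of other cell types. The T cell function lists (Treg signature, T helper effector genes and T cell trafficking) were tested only in the Treg and platelet comparisons, and a list needed 5 tested members. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Passing members were counted after adjustment over all genes and after adjustment over the list alone.

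Genes were named by a rule. It takes the 8 largest and 8 smallest log2 fold changes among genes past the threshold with a group mean of at least 10 CPM, leaving out predicted genes and pseudogenes. It adds the 2 members of each list with the smallest p, the most abundant member of each list of other cell types, and a fixed set with Pf4, Ppbp, Itga2b, Il10, Tgfb1, Arg1, Mrc1, Nos2 and Tnf, of which 1 further gene was not analysed here. Where fewer than 5 genes passed in a direction, the 5 with the smallest p are named with values only. Genes outside the rule are marked as chosen after their values were seen. Named genes that passed were selected on these same libraries. That their libraries lie on the same side of the other group is therefore largely fixed by the selection and is no separate support.

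Means and SD are normalised CPM unless plain CPM (without the normalisation factor) is stated. Where every library of a group had 0 counts, the fold is a lower bound against 3 counts over that group. With 1 to 3 counts in a group, a ratio with its 95% counting interval is given. Both are from plain CPM and cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Fitted fold changes of such genes depend on the prior count and are not bounds. The share of satellite gene models was taken over 12 gene models. In these at least 50% of the words of 12 bases match the mouse major satellite repeat. Shares of single libraries have a Wilson interval, which covers counting error only and not the spread between libraries. Correlations used permutation tests with 1e+05 permutations, and the test of the M1 satellite shares was an exact two-sided permutation test. The platelet share of an aggregate library was the scaled weight in a non-negative least squares fit of its CPM on the single Treg library and the mean platelet profile.

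The tests were checked on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per simulated comparison. At the fitted dispersion, a 4-fold change was recovered for 3 of 100 genes in the M1 depletion design, 1 of 100 in the design of M2 against M1 after depletion and 0 of 100 in the others simulated, and a 2-fold change for 0 of 100. At a dispersion of 0.05 the M1 design recovered 41 of 100 genes at 2-fold and 90 of 100 at 4-fold.

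Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter or one of 50 counts, a log2 fold change of at least 1, other sets of libraries or genes in the fit, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, permutations and figures.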

Results

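Pneumonia was induced in mice by Klebsiella pneumoniae instilled into the airways, and lavage cells were taken on day 5. The 16 libraries were 3 of M1 macrophages, 3 of M1 macrophages 3 days after platelet depletion, 1 of M2 macrophages, 3 of M2 macrophages 3 days after platelet depletion, 1 of single Tregs, 2 of Treg-platelet aggregates and 3 of platelets from peripheral blood. Total counts ranged from 15219002 to 17866727 in M1 controls, 18502673 to 19676258 in M1 depleted, 16348729 to 20237355 in M2 depleted and 23153720 to 23870948 in platelet libraries. The M2 control library had 12845141 counts, the single Treg library 8641237, and the aggregates 15364179 and 14134342. Gene models matching the major satellite repeat, a DNA repeat of mouse centromeres, took 22.8% ± 1.79 of the counts in M1 controls and 13.9% ± 2.72 in M1 depleted libraries (SD, n = 3 each). That difference had an exact permutation p of 0.1, the smallest that 3 against 3 can give. The share was 31.65% in the M2 control library (Wilson interval 31.62 to 31.67%) and 21.4% ± 6.08 in M2 depleted libraries (SD, n = 3). It was 32.24% and 29.11% in the aggregates and 13.34% in single Tregs (13.32 to 13.36%). The Wilson intervals cover counting error only, not the spread between libraries.

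**Figure D1:**
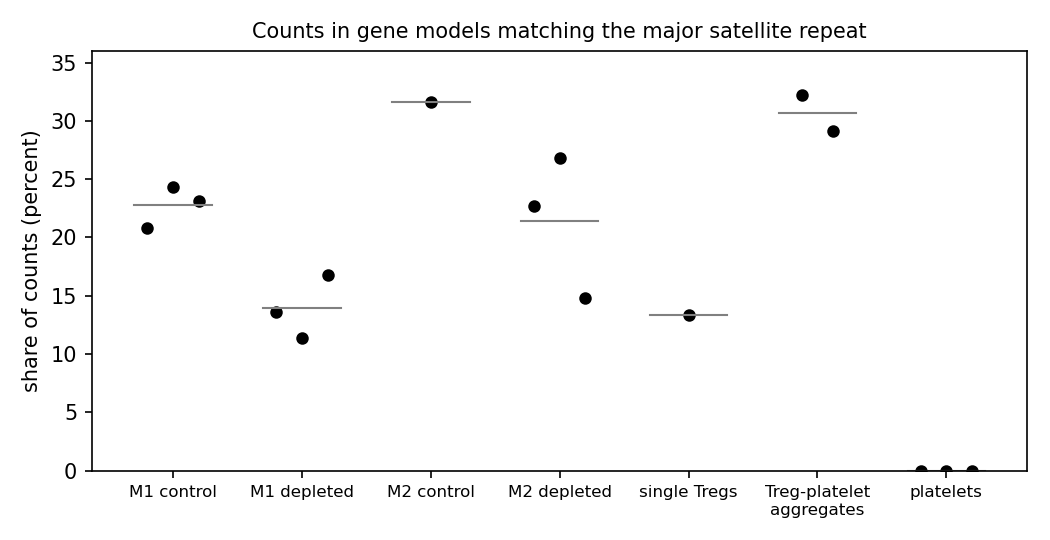
Share of counts, in percent, in the 12 gene models that match the mouse major satellite repeat, with 1 point per library and a line at each group mean. The M1 depleted libraries lie between 11.39 and 16.8%, below the M1 controls at 20.83 to 24.35%, and platelets lie near 0.

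The first comparison asked how M1 macrophages, the label used for a proinflammatory type, differed after platelet depletion. The neutrophil markers were higher in depleted M1 macrophages as a list, with 0 of 18 tested members passing alone (camera adjusted p = 2.94e-06; adjusted p = 0.592 with an estimated correlation). S100a8, a calprotectin subunit of neutrophils, had 2695 ± 3880 CPM in depleted and 289.5 ± 166 CPM in control libraries (SD, n = 3 each), and Lcn2, an iron-siderophore binding protein, had 1179 ± 1421 and 125.7 ± 134 CPM. The alveolar macrophage markers were lower as a list (camera adjusted p = 0.00293; adjusted p = 0.592 with an estimated correlation), with 0 of 19 members passing and 1 adjusted over the list alone. That member was Cd2, an adhesion molecule also on the T cell list, with 28.2 ± 6.87 CPM in controls and 0 counts in depleted libraries, at least 575-fold lower at an adjusted p of 0.828. Proinflammatory macrophage genes (0 of 27 passing, camera adjusted p = 0.0147) and glycolysis genes (0 of 17, camera adjusted p = 0.0222) were higher as lists. Erythroid markers were higher too (0 of 7 passing, 4 adjusted over the list alone, camera adjusted p = 0.0342), and these 3 lists had an adjusted p of 0.592 with an estimated correlation. Tnf had 279.5 ± 273 CPM in depleted and 57.1 ± 7.59 in control libraries, and Pkm, a pyruvate kinase, had 2647 ± 702 and 1147 ± 505. Hba-a1, an alpha globin with a near-identical second copy, had 130.2 ± 212 and 0.58 ± 0.373 CPM.

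The library M1 depleted 3 stood apart from the others. In plain CPM it held 6255.6 of S100a8, 289 of Il10 and 327.3 of Hba-a1, and 2013.8 of Lyz2, the macrophage lysozyme, where the other M1 libraries had 24565.2 to 45778.7. Without it the neutrophil list had an adjusted p of 0.136, the proinflammatory list 0.168, and the alveolar, glycolysis and erythroid lists passed. The proinflammatory list also missed the threshold without M1 control 1 (0.0505), M1 control 3 (0.165) or M1 depleted 1 (0.116). The erythroid list missed it without M1 control 1, 2 or 3 (0.0769 to 0.15), the alveolar list without M1 control 3 (0.991, with the direction changed to higher), and the glycolysis list without any library except M1 depleted 3.

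No single gene passed in edgeR among 18886 tested for M1 platelet depletion. An unadjusted p under 0.05 was found for 1051, close to the share of 0.05 that chance alone gives. DESeq2 called 152 genes, 71 higher and 81 lower, and limma-voom called 0. The smallest p belonged to genes with an adjusted p of 0.828. Copa, the coat protein of vesicles between Golgi and endoplasmic reticulum (mm10 chromosome 1, 172082529 to 172122330), had 207.1 ± 6.56 CPM after depletion and 94.9 ± 4.58 in controls, a log2 difference of 1.13 (SE 0.249). Cactin had 28.7 ± 2.57 and 5.58 ± 1.52 CPM. Itgam, an integrin of myeloid cells, had 656.1 ± 54.5 and 379.9 ± 29.99 CPM, and F13a1, a coagulation factor chain, had 556.4 ± 408 and 103.6 ± 31.1. The platelet chemokine Pf4 had 18.0 ± 5.47 CPM in depleted and 115 ± 117 in control libraries, and Ppbp had 1.77 ± 2.60 and 2.11 ± 2.62. Arg1, an arginase typical of M2 macrophages, had 272.4 ± 140 and 186 ± 84.9 CPM. Without M1 control 1, edgeR called 4 genes lower: Slc10a2, Olfr66, D730002M21Rik and Gm34730, the last 2 named after their values were seen. The lists that did not pass had adjusted p of 0.0516 to 0.947 by camera, and fry passed 0 of 23 lists, with a lowest adjusted p of 0.642.

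M2 macrophages, the label used for an alternatively activated type, were compared in the same way. In depleted M2 macrophages 529 genes rose and 9 fell against the control library in edgeR. Arg1 (chromosome 10, 24915221 to 24927484) rose from 0.0727 to 70.3 ± 44.7 CPM (SD, n = 3), a ratio of 826 with a counting interval of 148 to 32600 and an adjusted p of 0.0146. Cd86, a costimulatory ligand (chromosome 16, 36603869 to 36666081), rose from 0.436 to 38.5 ± 23.3 CPM, a log2 fold change of 6.44 (SE 0.958, adjusted p = 0.0129). Il12a, a chain of interleukin 12 (chromosome 3, 68690644 to 68698547), was at 0 in the control and at 40.6 ± 8.002 CPM after depletion, at least 166-fold higher (adjusted p = 0.0101). With them, 3 of 27 proinflammatory genes and 2 of 20 alternatively activated macrophage genes rose, the second gene of the latter being Egr2, a transcription factor at least 32.9-fold higher. The proinflammatory list had a camera adjusted p of 0.483, and the alternatively activated list 0.942.

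Lipid mediator genes that rose in M2 macrophages were Ptger2, a receptor for prostaglandin E2 at least 227-fold higher, and Ptges3, a cytosolic prostaglandin E synthase, at 149.2 ± 56.2 against 20.4 CPM. They were 2 of 21 tested, and 5 adjusted over the list alone (camera adjusted p = 0.145). Cholesterol synthesis had 2 of 20 members higher, Fdft1 (squalene synthase, at least 99.9-fold) and Pmvk (phosphomevalonate kinase, at least 19.2-fold), with a camera adjusted p of 0.616. Cell cycle genes had 2 of 23 higher, Mcm3 of the replicative helicase, at least 40.5-fold, and the proliferation marker Mki67, at 39.2 ± 6.12 against 0.364 CPM (camera adjusted p = 0.942). Abca1, a cholesterol exporter on the phagocytosis list, rose from 3.998 to 108.9 ± 58.0 CPM, 1 of 24 members (camera adjusted p = 0.542), and the heat shock gene Hsph1 was at least 56.9-fold higher, with Egr2 2 of 17 immediate early and heat shock genes (camera adjusted p = 0.616). Relb, an NF-kB subunit, rose with a ratio of 389 (133 to 1890), 1 of 21 members and 3 adjusted over the list alone (camera adjusted p = 0.28). The largest bounds belonged to Gabarapl1, an autophagy protein at least 440-fold higher, and to Gas7 and Bid, a proapoptotic protein, each at least 396-fold. Hdlbp, an RNA-binding protein (chromosome 1, 93405940 to 93478815), reached 91.5 ± 10.1 CPM from 0 counts, at least 357-fold higher with an adjusted p of 0.00595.

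The genes that fell in depleted M2 macrophages included Parn, a poly(A) ribonuclease, at 10.4 ± 5.39 against 131.6 CPM (log2 fold change −3.66, SE 0.650). Cpped1 was at 6.55 ± 2.96 against 102.6 CPM, and Lmf2, a lipase maturation factor (chromosome 15, 89351004 to 89355659), at 31.5 ± 10.9 against 142.8 CPM with an adjusted p of 0.0486. Smpd2, a sphingomyelinase, and Drosha, a microRNA processing enzyme, fell with log2 fold changes of −3.92 and −6.25. Tln2, Crx and Cyp2f2 fell too, Cyp2f2 with a ratio of 0.000329 (8.33e-06 to 0.00184). The median of all genes lay at a log2 fold change of 0.91, or 0.84 with RLE factors. All 29 named genes that passed had every depleted library on the same side of the control library. Of the 529 genes that rose, 303 had 0 counts in the control library and 385 (72.8%) had 3 or fewer. That library had 3 or fewer counts for 359 of 5325 genes that averaged 20 plain CPM in the other macrophage libraries, where each of the others had 11 to 88. Of 18886 genes, 2747 had an unadjusted p under 0.05, and DESeq2 called 2727, but edgeR called 3 with all 16 libraries in the fit and 0 on the M2 libraries alone, and limma-voom called 0. No list passed of 23 (camera adjusted p = 0.145 to 0.997, lowest fry adjusted p = 0.0535).

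**Figure D2:**
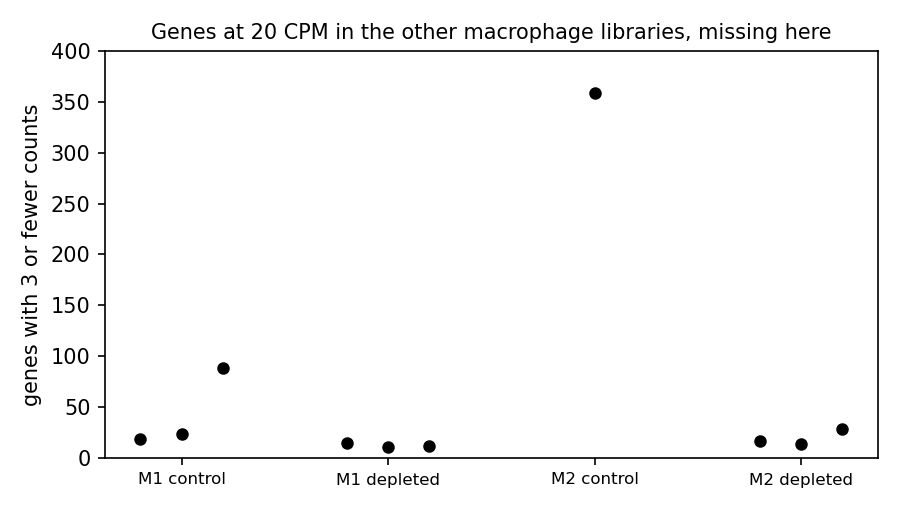
Genes with 3 or fewer counts in a macrophage library among those that average at least 20 CPM in the other macrophage libraries, with 1 point per library. The M2 control library has 359 such genes, and the other 9 libraries have 11 to 88.

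The difference between the effects of depletion in M2 and in M1 macrophages was tested as an interaction. It passed for 370 genes, 367 with a more positive effect in M2 and 3 with a more negative one, with the median of all genes at 0.90 (0.82 with RLE factors). Its M2 side rests on the control library in which 359 of 5325 genes had 3 or fewer counts, as had 301 of the 367 genes. Arg1 was among them, at 70.3 ± 44.7 against 0.0727 CPM in M2 and 272.4 ± 140 against 186 ± 84.9 in M1 macrophages (adjusted p = 0.0245). Il12a and Cd86 (adjusted p = 0.0188 each), Ptger2 (0.0177) and Egr2 (0.0183) passed as well, as did Itm2c, a membrane protein, and Tifa, a TRAF-binding adaptor, at adjusted p of 0.00933 and 0.00939. Lmf2 had a more negative effect in M2 macrophages, with a log2 difference of −3.08 (SE 0.614), as had Calb1, a calcium-binding protein, and the predicted gene 9430038I01Rik, named after its values were seen. By list, 2 of 27 proinflammatory, 2 of 20 alternatively activated, 2 of 20 cholesterol synthesis, 2 of 17 immediate early and heat shock, 1 of 23 cell cycle and 1 of 21 lipid mediator genes passed. Of the lists, 0 of 23 passed (camera adjusted p = 0.13 to 0.998; lowest fry adjusted p = 0.123). The count fell to 236 without M1 control 1, 243 without M1 control 2, 198 without M1 depleted 1, 178 without M1 depleted 2 and 235 without M2 depleted 1. It was 0 with limma-voom and 0 with all 16 libraries in the fit.

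M2 and M1 macrophages were next compared after platelet depletion, 3 libraries against 3. Phagocytosis and efferocytosis genes were lower in M2 as a list (camera adjusted p = 1.49e-10; adjusted p = 0.265 with an estimated correlation), with 0 of 24 members passing and 6 adjusted over the list alone. Msr1, a scavenger receptor (chromosome 8, 39581685 to 39642673), had 71.2 ± 24.1 CPM in M2 and 305 ± 92.2 in M1 (SD, n = 3 each), and the scavenger receptor Marco had a ratio of 0.00418 (0.000504 to 0.0152). MHC class II genes were lower as a list (0 of 11 passing, camera adjusted p = 8.07e-05; adjusted p = 0.635 with an estimated correlation). Cd74, the invariant chain, had 989 ± 568 and 4829 ± 3422 CPM. Monocyte markers (0 of 16, camera adjusted p = 0.000382) and alveolar macrophage markers (0 of 19, camera adjusted p = 0.000618) were lower, at adjusted p of 0.515 and 0.54 with an estimated correlation. Neutrophil markers were higher (0 of 18, camera adjusted p = 0.000103; adjusted p = 0.635 with an estimated correlation). Mmp9, a gelatinase of neutrophils, had 270.1 ± 125 CPM in M2 and 29.8 ± 22.1 in M1 macrophages. Oxidative phosphorylation (0 of 25, camera adjusted p = 0.000168), pan-macrophage markers (0 of 13, 0.0251) and alternatively activated genes (0 of 20, 0.0468) were lower, at adjusted p of 0.64, 0.635 and 0.635 with an estimated correlation. Arg1 had 70.3 ± 44.7 CPM in M2 and 272.4 ± 140 in M1 macrophages.

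The library M2 depleted 3 held 14164.1 plain CPM of S100a8, 798.3 of Il10 and 560.3 of Lyz2, where the other M2 depleted libraries had 1881.7 and 1916.2 of S100a8 and 12065.1 and 19799 of Lyz2. Without it the neutrophil and oxidative phosphorylation lists of M2 against M1 missed the threshold (adjusted p = 0.313 and 0.129). The phagocytosis, MHC class II, monocyte and alveolar lists passed without each of the 6 libraries in turn, the alternatively activated list in 3 of the 6 cases and the pan-macrophage list in 2. The other 15 lists had camera adjusted p of 0.256 to 0.828, and fry passed 0, with a lowest adjusted p of 0.278. No gene passed in edgeR for M2 against M1 after platelet depletion. An unadjusted p under 0.05 was found for 945 of 18886 genes, about the share of 0.05 that chance alone gives. DESeq2 called 111 (55 higher, 56 lower) and limma-voom 0. Acp5, an acid phosphatase, had 80.4 ± 8.80 CPM in M2 and 434.6 ± 79.2 in M1 macrophages (log2 difference −2.44, SE 0.425, adjusted p = 0.944).

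**Figure D3:**
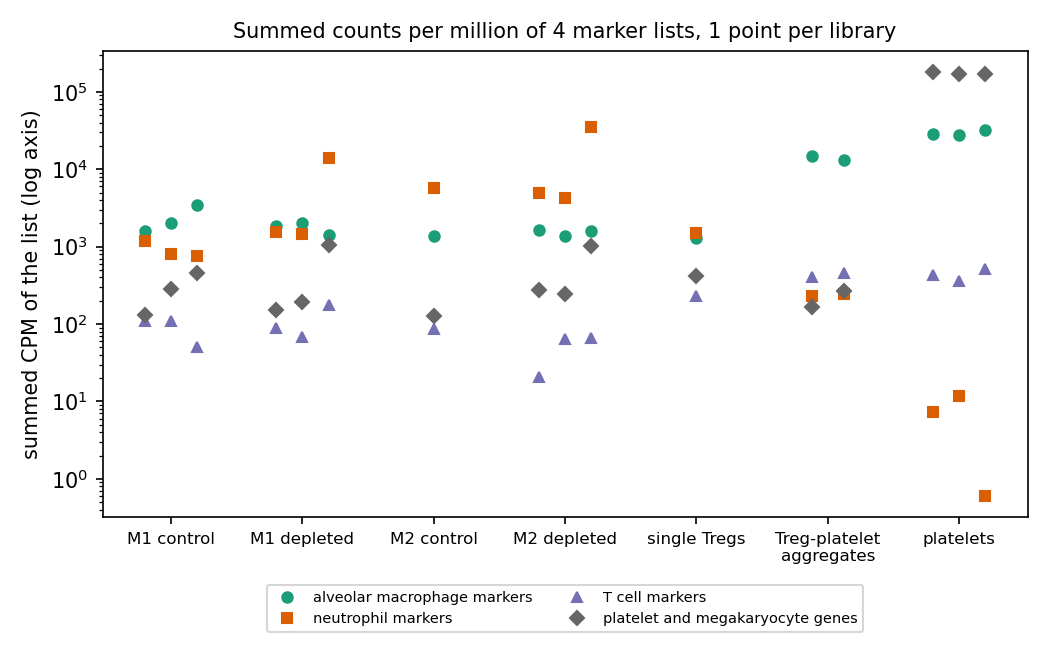
Summed plain CPM of 4 marker lists on a log axis, with 1 point per library. The third library of both depleted groups has the highest neutrophil sums (14012.5 and 34973.9), aggregates have the highest alveolar sums among nucleated cells (14887.8 and 13148.4), and the alveolar sum of platelets is mostly Cd9.

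Without depletion, the M2 control library was compared with 3 M1 control libraries. In M2, 533 genes were lower and 13 higher, with the same control library in which 359 of 5325 genes had 3 or fewer counts. Cd86 fell to 0.436 from 64.8 ± 8.67 CPM (log2 fold change −7.19, SE 0.992, adjusted p = 0.00981), and Arg1 had a ratio of 0.000393 (9.96e-06 to 0.00219). Genes at 0 counts in M2 included Il12a (at least 118-fold lower), Egr2 (at least 147-fold), Itm2c (at least 448-fold), Gstp1, a glutathione transferase (at least 330-fold), and Il10ra, an interleukin 10 receptor chain (at least 374-fold). Among the higher genes were Itpr2, a calcium channel of the endoplasmic reticulum, at 227.6 against 25.1 ± 11.2 CPM, and Ggta1, a galactosyltransferase, at 184.7 against 23.7 ± 12.5. Enpp5 had 60.8 CPM in M2 and 0 counts in M1 controls, at least 1050-fold higher. Neutrophil markers were higher as a list (0 of 18 passing, camera adjusted p = 6.84e-06; adjusted p = 0.955 with an estimated correlation), with S100a8 at 2753 against 289.5 ± 166 CPM. Phagocytosis genes were lower (1 of 24 passing, 7 adjusted over the list alone, camera adjusted p = 0.000537; adjusted p = 0.955 with an estimated correlation), Abca1 being the member that passed, at 3.998 against 133.6 ± 67.2 CPM. Alveolar markers were lower (0 of 19, camera adjusted p = 0.0488; adjusted p = 0.955 with an estimated correlation). The alveolar call was lost without M1 control 1 (0.0501) or M1 control 3 (0.463). The other 20 lists had camera adjusted p of 0.168 to 0.984. By fry none of the 3 passed, and 2 others did, cell cycle and lipid mediator genes, both lower (adjusted p = 0.0463 each). All 27 named genes that passed had the M2 library on the same side of every M1 control, and the median of all genes lay at −0.79 (−0.71 with RLE factors). DESeq2 called 2787 genes, limma-voom 0, and edgeR 2 with all 16 libraries in the fit and 0 on these 4 libraries alone.

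The aggregates were compared with the library labelled single Tregs. In plain CPM, pan-macrophage markers summed to 43360.3 in that library, 36689 and 43040.1 in the aggregates and 39358.6 to 59040.5 in M1 controls. The Treg signature summed to 1283.3 in that library and 1348.4 to 2214.6 in the macrophage libraries. Among its tested members, Capg had 478.8 normalised CPM in that library and Batf, the next highest, 53.8. The normalisation factor of that library was 2.40, so its plain CPM are higher than its normalised CPM. The sum of the Treg signature there thus rests largely on Capg. T cell markers summed to 233.2 plain CPM in that library, above the 20.9 to 177.2 of the macrophage libraries. The platelet libraries had 363 to 514.5 on the same list, so a sum at that level is not particular to T cells. Alveolar macrophage markers were higher in aggregates as a list (camera adjusted p = 5.04e-13; adjusted p = 0.203 with an estimated correlation; fry adjusted p = 0.00844), with 0 of 21 members passing and 11 adjusted over the list alone. Chil3, a chitinase-like protein with a near-identical copy (chromosome 3, 106147554 to 106167564), had 18330 ± 5648 CPM in aggregates (SD, n = 2) and 344.6 in single Tregs. Plet1, a surface protein (chromosome 9, 50494525 to 50505482), had 673.4 ± 139 and 0.2002 CPM. Mrc1, the mannose receptor, had 271.7 ± 101 CPM and 0 counts in single Tregs, at least 1120-fold higher at an adjusted p of 0.463. Lung epithelium markers were higher as a list (0 of 6, camera adjusted p = 0.000846) and monocyte markers lower (0 of 11, 1 adjusted over the list alone, camera adjusted p = 0.0035), both at an adjusted p of 0.286 with an estimated correlation. Only 6 of 19 lung epithelium genes were tested, 1 was left without aggregate 1 or without aggregate 2, too few to test again, and the plain CPM of all 19 summed to 253.8 and 247.2 in aggregates but 304.1 in single Tregs. The monocyte call was lost without aggregate 1 (0.175) or aggregate 2 (0.649), each time with 1 library against 1. Saa3, an acute phase protein, had 0.906 ± 0.0396 CPM in aggregates and 1166 in single Tregs. Platelet genes did not pass as a list (0 of 31 passing, 3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.934). Clec1b, a platelet receptor, had 32.1 ± 7.35 against 0.2002 CPM, and Pf4 had 4.62 ± 6.12 against 59.3. The Treg signature had 0 of 10 members passing, and the 22 lists that did not pass had camera adjusted p of 0.0637 to 0.934.

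No gene passed in edgeR among 13364 for aggregates against single Tregs, with 485 at an unadjusted p under 0.05, 558 called by DESeq2 and 362 by limma-voom. Without aggregate 1 edgeR called 208 genes, and without aggregate 2 it called 209, but there 1 library faces 1 and all spread comes from the platelet libraries, so these counts are not comparable with the 0. The median of all genes lay at 0.26, or −0.02 with RLE factors. The smallest adjusted p was 0.165. Pcmt1, a protein repair methyltransferase, and Ehd4, an endocytic protein, had 43.6 ± 23.4 and 22.8 ± 7.34 CPM in aggregates and 0 counts in single Tregs, at least 178-fold and 94.0-fold higher, beside 3812 ± 728 and 1917 ± 490 CPM in platelets. Cd81, a tetraspanin, had 114.3 ± 41.9 and 0.2002 CPM. In plain CPM, Cd3e, a chain of the T cell receptor complex chosen after its values were seen, was at 74.9 in the single Treg library and at 0 counts in both aggregates. Lyz2 was at 33719.9 in single Tregs and 25596 and 30827.4 in aggregates. The least squares weight of the platelet profile was 0% in both aggregates (R² of 0.649 and 0.698). It was 77.7 and 69.3% on a log2 scale (R² of 0.414 and 0.446). Without the 20 highest genes of either profile it was 6.79 and 6.02% (R² of 0.133 and 0.212). The weight thus depended on the setting.

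Against platelets, 230 genes were higher in aggregates and 379 lower in edgeR (37.8% higher), and with RLE factors 402 were higher and 379 lower (51.5%). The balance depended on the method, with 5536 higher and 1110 lower in DESeq2 (83.3%), 5023 and 673 in limma-voom (88.2%), and 6365 and 1010 in edgeR with all 16 libraries in the fit (86.3%). Platelet and megakaryocyte genes fell together, 27 of 31 (camera adjusted p = 2.56e-39; adjusted p = 0.686 with an estimated correlation). Ppbp, a platelet chemokine (chromosome 5, 90768518 to 90770063), was at 0.677 ± 0.0771 CPM in aggregates (SD, n = 2) and 47440 ± 12360 in platelets (SD, n = 3), a log2 fold change of −16.08 (SE 0.623, adjusted p = 0.00374). Pf4 (chromosome 5, 90772435 to 90773383) fell to 4.62 ± 6.12 from 25420 ± 8180 CPM, Itga2b, the integrin of platelets, had a log2 fold change of −16.39, and P2rx1, an ATP-gated channel, was at least 9960-fold lower. Erythroid markers fell, 5 of 8 (camera adjusted p = 1.82e-08; adjusted p = 0.686 with an estimated correlation), among them the beta globin Hbb-bt, which has near-identical relatives, at least 24600-fold lower. Alveolar macrophage markers were higher, 11 of 21, with 1 lower (camera adjusted p = 0.000498; adjusted p = 0.691 with an estimated correlation). Atp6v0d2, a proton pump subunit, was at least 18900-fold higher, Ear1, which has close relatives, at least 14700-fold, and Abcg1, a cholesterol exporter, was at 1181 ± 320 against 0.465 ± 0.323 CPM. Alternatively activated genes had 3 of 16 members higher (camera adjusted p = 0.0446), Chil3 with a log2 fold change of 14.89 and Mrc1 at least 9100-fold among them, and interferon response genes 2 of 19 lower (camera adjusted p = 0.00938). Both had an adjusted p of 0.691 with an estimated correlation. Clec7a, the receptor Dectin-1, was at least 21700-fold higher, and Cd68, a macrophage lysosomal protein, reached 633.3 ± 9.66 from 0.105 ± 0.0628 CPM.

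For aggregates against platelets, the alveolar list missed the threshold without aggregate 1 (0.31) or aggregate 2 (0.207), and the alternatively activated list without platelets 2 (0.0955), aggregate 1 (0.331) or aggregate 2 (0.2). The other 20 lists had camera adjusted p of 0.0685 to 0.98. Fry passed 14 lists, but its direction was opposite to that of camera for 8 of the 25 lists. The same held for 8 of 25 lists in single Tregs against platelets. All 52 named genes that passed had each aggregate on the same side of each platelet library. The median of all 13364 genes lay at 4.59 (5.24 with RLE factors), and 6065 genes had an unadjusted p under 0.05. The count of 609 was 0 without platelets 1 and 26 without platelets 2.

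The library labelled single Tregs had 145 genes higher and 254 lower than platelets (36.3% higher), and 309 higher and 282 lower with RLE factors (52.3%). DESeq2 gave 4113 higher and 1291 lower (76.1%), limma-voom 3187 and 546 (85.4%), and edgeR with all 16 libraries in the fit 5165 and 820 (86.3%). Platelet genes fell, 22 of 31 (camera adjusted p = 1.1e-29; adjusted p = 0.799 with an estimated correlation), with Gp1bb, a glycoprotein Ib chain, at least 17500-fold lower, the tubulin Tubb1 at least 7050-fold and the coagulation factor F5 at least 3690-fold. Erythroid markers fell, 3 of 8 (camera adjusted p = 9.73e-06; adjusted p = 0.799 with an estimated correlation). NF-kB targets were higher as a list (1 of 18 passing, 2 adjusted over the list alone, camera adjusted p = 0.0259; adjusted p = 0.799 with an estimated correlation). The member that passed was Nfkbia, the NF-kB inhibitor, at 285.1 against 0.124 ± 0.135 CPM. Interferon response genes were lower (1 of 19 passing, camera adjusted p = 0.0116; adjusted p = 0.949 with an estimated correlation), the member being Isg20, at least 1500-fold lower. Oxidative phosphorylation was lower by camera (1 of 25 passing, adjusted p = 0.0343; adjusted p = 0.949 with an estimated correlation), although the median member lay at 0.41, its mean at −0.26 and fry gave the upward direction. Genes that rose, in a library with the pan-macrophage sum given above, included Cd14, a receptor for bacterial lipopolysaccharide, with a ratio of 23800 (8150 to 115000). Others were Tyrobp, with a ratio of 39800 (11000 to 329000), and Fn1, fibronectin, at 670 against 12.4 ± 5.70 CPM. Cd68, Fpr1, Chil3 and Ccl6 were higher as well. Hsd3b2, a steroid dehydrogenase, was at least 17500-fold higher.

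For single Tregs against platelets, the oxidative phosphorylation call was lost without each platelet library (0.065 to 0.108), the NF-kB call without platelets 2 (0.065) and the interferon call without platelets 2 (0.0523). The 20 lists that did not pass had camera adjusted p of 0.213 to 0.973, and fry passed 14. All 38 named genes that passed had the Treg library on the same side of each platelet library, and the median of all genes lay at 3.07 (4.32 with RLE factors). The count of 399 genes was 0 without platelets 1 and 0 without platelets 2, while 4887 genes had an unadjusted p under 0.05 with all libraries.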

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

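The test of transcripts missing from the M2 control library was chosen after the result was seen, and that with M1 controls reduced to 1 library was added after seeing the data but before its own result.

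The interaction of platelet depletion with macrophage type passed for 370 genes in edgeR, but for 0 in limma-voom and 0 with all 16 libraries in the fit, and its M2 side rests on 1 control library. The log2 differences were 13.49 for Golga2, 13.48 for Vps26c, 13.32 for Gabarapl1, 13.29 for Cstf1, 13.27 for Trp53inp2, 13.23 for Itm2c, 13.21 for Il10ra and 13.20 for Tifa. From the lists they were 12.65 for Fdft1, 12.45 for Ptger2, 12.09 for Hsph1, 11.57 for Il12a, 10.79 for Mcm3, 10.62 for Egr2, 10.15 for Pmvk, 9.23 for Arg1 and 6.49 for Cd86. The negative differences were −3.08 for Lmf2 and −10.45 for Calb1. Where the M2 control library was at 0 counts, these fitted values depend on the prior count and are not bounds.

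The pattern weighed is the excess of genes higher in depleted M2 macrophages than in the lone control library. An effect of a single control library was predicted to call many genes higher for M1 depletion with M1 controls reduced to 1 library, each in turn. No gene was called higher in edgeR, but this cannot exclude such an effect. The M1 comparison had called 0 genes with all its controls too. Among genes that averaged 20 plain CPM in the other macrophage libraries, M1 controls had 3 or fewer counts for 19 to 88, against 359 in the lone M2 control library. Transcripts missing from that library may account for part of the calls. Of the genes called higher, 72.8% had 3 or fewer counts there. These genes were selected as higher than that library, which raises the share, so the share decides nothing. At the fitted dispersion the M2 depletion design recovered 0 of 100 simulated 4-fold changes, so mainly larger differences could pass. A true absence in the cells also gives the same counts, so the explanations cannot be told apart in 1 library. A difference between M2 and M1 macrophages in their response to platelet depletion stays open and untested by any second M2 control.

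For M1 platelet depletion, 10 of 10 splits of the 6 libraries called at least the 0 genes of the real split, and the highest other split called 0. For M2 against M1 after platelet depletion, 10 of 10 splits called at least the real 0 and the highest other split called 1. With 0 genes in the real split every split calls at least as many, so neither test decides anything, and 10 splits are also too few for a share under 0.05. Over the platelet list, the median log2 fold change in depleted M1 macrophages was 1.18, with a lower quartile of −0.43 and 13 of 21 genes positive, so members went both ways.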

How the results depend on the processing

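Tests without the third depleted libraries, without satellite gene models, on the second columns, with M1 controls reduced to 1 library and of lists without single libraries were chosen after seeing the data. Genes passing are given for M1 depletion, M2 depletion, the interaction, M2 against M1 depleted, M2 against M1 controls, aggregates against Tregs, aggregates against platelets and Tregs against platelets, where the values above are 0, 538, 370, 0, 546, 0, 609 and 399. DESeq2 gave 152, 2727, 1987, 111, 2787, 558, 6646 and 5404. Limma-voom gave 0 for each of the 5 macrophage comparisons, then 362, 5696 and 3733. Without a filter the interaction had 591, aggregates against Tregs 71, aggregates against platelets 1125 and Tregs against platelets 907; M1 depletion had 1 (Cd2, lower) and M2 against M1 depleted 2 (Acp5 lower, Enpp5 higher). All 16 libraries in the fit gave 3 for M2 depletion (Gas2l1, Pea15a and Ubash3b, chosen after their values were seen), 0 for the interaction, 2 for M2 against M1 controls (Pea15a, Ubash3b), 178, 7375 and 5985. Only the libraries compared gave 0 for M2 depletion and 0 for M2 against M1 controls. Without satellite models aggregates against Tregs had 14. The platelet share was 77.7 and 69.3% on the log2 scale, and 6.79 and 6.02% without the 20 highest genes. The cause was not tested, except that fewer libraries leave fewer degrees of freedom. Leaving out 1 library gave 0 to 4 for M1 depletion, 396 to 557 for M2 depletion, 178 to 390 for the interaction, 0 to 0 for M2 against M1 depleted, 384 to 528 for M2 against M1 controls, 208 to 209 for aggregates against Tregs (with platelet spread alone where an aggregate is left out), 0 to 831 for aggregates against platelets and 0 to 494 for Tregs against platelets. Counts stayed within 1.5 times under RLE factors, the stricter filter, the fold threshold, the second columns and without the third depleted libraries (M2 depletion 597, interaction 334). No named gene that passed changed sign under any alternative, but these genes were selected on the same libraries, so that is no separate support. Over all alternatives they lost the call 126 times for M2 depletion, 97 for the interaction and 113 for M2 against M1 controls. They lost it 138 times for aggregates against platelets and 99 for Tregs against platelets. Named genes that had not passed changed sign 23, 14, 21, 22, 3, 7, 6 and 5 times in the same order, over all alternatives. No paired analysis was possible because the library codes in the labels are unique to each sample and name no shared animal. The interaction on only the libraries compared was not run, since its groups are all those of the fit. Depth limits genes at low counts most in the single Treg (8641237 counts) and M2 control (12845141 counts) libraries, where a gene at 0 counts allows up to 3.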

Other observations

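The tests of what the aggregate libraries hold were chosen after the result was seen, except the share of genes with more CPM in platelets. Both tests of the satellite share were chosen before, over the 13 libraries of nucleated cells. The relations in the 10 macrophage libraries alone were not part of them.

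The third library of both depleted groups stood apart from the other macrophage libraries in several lists. In plain CPM, Il10, an anti-inflammatory cytokine, was at 289 in M1 depleted 3 and 798.3 in M2 depleted 3, and between 0 and 10.5 in the other 8 macrophage libraries. Tnf was at 501.8 and 935.7 in the same libraries, and between 43.2 and 346.3 in the others. The summed proinflammatory list was 17458 and 22085, where the others had 3225.6 to 5807.5 in M1 and 3312.1 to 5695.9 in M2. MHC class II transcripts were lowest there among macrophages, at 3202.4 and 487.1, and T helper effector genes, which share Tnf with the inflammatory lists, summed to 569.9 and 971.6 (61.6 to 371.1 in the others). Neutrophil markers summed to 14012.5 and 34973.9 there and 754.1 to 5647.3 in the others, and pan-macrophage markers to 12563.5 and 11277.5 against 17612.8 to 59040.5.

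In plain CPM, the aggregates held 1754.3 and 2042.8 of Ear2, 1482.7 and 1155.8 of Lpl, a lipoprotein lipase, and 365.3 and 215.5 of Siglecf, a sialic acid receptor of alveolar macrophages and eosinophils. Single Tregs had 0.1, 180.6 and 0.1 of these genes, which were chosen after their values were seen. Arg1 was at 0 in both aggregates and 146.9 in single Tregs, and Il2ra, an interleukin 2 receptor chain, was at 4 and 5 against 31. The Treg library held 40727 CPM of olfactory and vomeronasal receptor genes, the macrophage libraries 6559 to 18028 and platelets 94.6 to 145.6. Ribosomal protein genes took 0.126 to 0.139% of the counts in platelets and 3.09% in single Tregs.

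The first pattern weighed is the transcripts of the aggregate libraries. Alveolar macrophages among the sorted aggregates are a candidate source, since the alveolar list without Cd9 summed to 10991 and 10298 CPM there, against 2004 in the highest macrophage library and 696 in single Tregs, with Chil3 at 29775.1 and 22793.2; the sort named in the labels selects Treg-platelet aggregates. For T cells as the main RNA source, T cell markers summed to 407.1 and 459.8 CPM in the aggregates. Both lay above the 177.2 of the highest macrophage library, which met the prediction for this source. Cd2, which is also on the alveolar list, carries that outcome. Without Cd2, a list added after that result, the sums were 46.0 and 58.8 CPM against 177 in the highest macrophage library, which argues against this source. The outcome thus depends on whether Cd2 is counted, and the platelet libraries had 363 to 514.5 CPM on the list with Cd2. RNA of platelets like those from blood is argued against by the platelet list. In aggregates that list stood at a median of 0.00627% of its platelet CPM (quartiles 0.00277 and 0.0546%). Of the 393 genes higher in aggregates than in single Tregs at an unadjusted p under 0.05, 347 had counts in platelets. They stood at 67.7% (18.3 and 172%). That gap is no separate support, since these genes were selected as high in aggregates and the list holds platelet genes. Only 485 of 13364 genes had such a p in either direction, below the share of 0.05 that chance alone gives. The planned test went the other way from the platelet list. Of all 393 genes, 84.5% had more CPM in platelets than in single Tregs, over the 80% set before (23.6% of all tested genes). With over 3 Treg counts 128 of 148 had more (12.9% of all tested genes at that level), and with 3 or fewer 83.3% (66.1% at that level). But 98% had more in macrophages too (49.9% of all tested genes). That share was 99.2% with 3 or fewer Treg counts (97% of all tested genes at that level). The genes were selected as lower in single Tregs than in aggregates, which raises such shares.

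The other pattern weighed is the satellite share. Genomic DNA in the libraries may raise it, but over the 13 libraries of nucleated cells the share and the CPM of olfactory and vomeronasal receptors had a Spearman rho of 0.489 (permutation p = 0.0919, adjusted p = 0.184, interval −0.085 to 0.819) and a Pearson r of −0.0112 (permutation p = 0.977). The single Treg library stood apart, with 40727.45 receptor CPM at a satellite share of 13.34%, where the others had 6559.37 to 18028.3 CPM. A relation over the libraries without it was not computed, so the low r does not argue against genomic DNA. The prediction did not name the 10 macrophage libraries alone. There rho was 0.879 (permutation p = 0.00165, adjusted p = 0.0066) and r 0.882 (permutation p = 7e-04, adjusted p = 0.0028). Without the 2 libraries farthest from the median r was 0.798. Fewer reads from messenger RNA are not decided either, with a rho of −0.104 for genes at 10 counts after thinning (permutation p = 0.734, interval −0.619 to 0.474, r −0.142), and 0.248 in macrophages (permutation p = 0.491, r 0.125, but 0.838 without the 2 farthest libraries). In all, 4 relations were computed, and a difference between the cell groups in transcription of the repeat stays open and untested.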
